A study of Danio rerio with 8 samples.

How the data were processed

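RNA sequencing libraries from the cardiac ventricle of adult zebrafish were compared between cox7a1 homozygous mutants and their wildtype siblings 7 days after cryoinjury, in which a region of the ventricle is killed by freezing. Each of the 8 libraries held RNA pooled from 5 ventricles, and there were 4 pools per genotype. Per the labels' protocols, libraries were made with a directional Illumina kit, so reads keep the strand of the transcript. Per the file headers, the authors counted reads with featureCounts 2.0.3 over exons grouped by gene, with the strand setting 2 (reverse stranded) and the Ensembl 109 annotation of GRCz11. The header's command has no option for read pairs, for reads mapped to several places or for reads shared by overlapping genes. FastQC, MultiQC, fastp and STAR are named in the submitters' processing notes, and their versions are not given in the sources used here.

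The deposited values are raw read counts per gene, 1 column per pool, with 32520 gene rows and no row that names no gene. The deposited exon length of each gene, in bases, was used for checks of gene length. No column of per-sample values was left unused (0 columns). Column names were matched to the library numbers in the labels, which are not the replicate numbers of the sample titles. Replicate numbers in the text are those of the titles. Symbols were taken from a table of gene IDs and symbols, in which 29201 of the 32520 IDs had a symbol. Many symbols in it are upper-case human-style names, 6314 rows share a symbol with another row, and symbols are printed as that table gives them. Paralogs that share sequence lose reads that map to several places, since such reads were not counted, so levels of near-identical copies such as the hsp70 genes are uncertain. No reference genome of this build was used here, so GC content was not checked.

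Total counts ran from 41556101 to 69057989 per pool, and 7094 gene rows had no count in any pool. Genes were filtered with filterByExpr by genotype at a minimum count of 10, which left 17949 genes. Libraries were scaled with TMM factors, and the levels printed are CPM values, which are counts scaled to the library size, computed from the deposited counts with these factors. On the log2 scale a prior count of 2 was added. Genotypes were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. A positive log2 fold change means a higher level in mutant pools. The level of cox7a1 was also compared with a two-sided exact permutation test of the 8 log2 CPM values, which cannot go below 0.0286 for 4 pools against 4. The pools are separate groups of fish, so p-values measure the spread between pools, and the spread between single fish was not measured.

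In advance, 36 gene lists were fixed for the respiratory chain, metabolism and stress, the response to injury, sample handling and time of day, and cell types that a ventricle pool could hold. Of 929 list members, 689 were matched by symbol, 189 after a paralog suffix was dropped and 51 were not matched. Lists with at least 5 tested members (34 of the 36) were tested with camera (limma 3.58.1) at the preset inter-gene correlation of 0.01, against all other tested genes. The test was repeated with an estimated correlation, and with fry, which asks whether a list's genes move on balance one way and, in a second test, whether they change in either direction. The named genes were also fixed by a rule. It takes cox7a1; then, among genes past the threshold with an average log2 CPM of at least 1, no overlap between the genotypes and a symbol that is not a clone-style name, the 12 largest rises and the 12 largest falls; then up to 4 members with the smallest p of each list, and every member of the Cox7a family. Clone-style prefixes written in capitals were taken as such only where digits follow, so that real symbols beginning with the same letters stayed in. Of the 12 largest falls, 1 gene is not reported here, nor is a gene family that holds it. The rule had 181 higher and 112 lower genes to choose from. Genes named outside it are said to be chosen after their values were seen.

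Alternatives set before the data were examined were other scaling (DESeq2's median-of-ratios factors, library totals alone, or mitochondrial genome and haemoglobin genes left out), other filters (none, or a CPM of at least 1 in at least 4 pools), other tests (DESeq2 1.42.0 and limma-voom), a replicate block, 1 surrogate variable (sva 3.50.0), each pool left out in turn, other thresholds, and the other list tests. After the data were examined, 5 alternatives were added: a smooth trend of each library on log2 exon length removed through an offset (lowess span 0.3), chromosome 15 left out of the counts, chromosome 15 left out of the lists, members of the fixed lists left out of gene families collected by symbol, and cox7a1 measured against the mean of 19 other nuclear subunits of complex IV.

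The fits were tested on simulated counts drawn for the real genes at the real library sizes, with 200 genes changed. In the simulated comparison of mutant with wildtype (17668 genes), edgeR recovered 10.4% of the genes changed by 1.5-fold, 53.1% at 2-fold, 86% at 4-fold and 95.8% at 8-fold, and 4.8% of its calls were false. DESeq2's calls in the same simulation (17949 genes) were 18.3% false. The counts were drawn with edgeR's own dispersions, without a length trend, an outlying pool or correlation between genes. The simulation may therefore favour edgeR and does not match the real pools in these respects. No 2 libraries of a genotype agreed within sampling noise, since chi-square per degree of freedom between libraries of 1 genotype was 40.6 or more.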

Results

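Gene expression was measured by RNA sequencing in the injured cardiac ventricle of adult zebrafish homozygous for a cox7a1 mutation and of their wildtype siblings. Cox7a1 is a subunit of cytochrome c oxidase, complex IV of the mitochondrial respiratory chain, and the study asked how it affects the response of the heart to injury. Each genotype had 4 pools of 5 ventricles, taken 7 days after cryoinjury. Total counts were 53597730, 51889237, 52499319 and 49788133 in wildtype replicates 1 to 4, and 41556101, 47461164, 48108612 and 69057989 in mutant replicates 1 to 4. Genes of the mitochondrial genome took between 13.33% and 17.38% of the counts in each pool. The first principal component of the log2 levels held 25.8% of the variance and separated the genotypes, with wildtype pools from -54.2 to -3.1 and mutant pools from 19.7 to 38.5.

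The transcript of the targeted gene was less abundant in mutant ventricles but was still detected in each of them. The gene cox7a1 (ENSDARG00000069464; GRCz11, chromosome 15, 20403084 to 20405796, plus strand, 952 exonic bases) averaged 246.1 CPM ± 41.6 (SD, n = 4) in wildtype and 113.7 CPM ± 57.7 (SD, n = 4) in mutant pools. The wildtype pools held 209.7, 278, 285.9 and 210.6 CPM and the mutant pools 59.52, 113.1, 88.46 and 193.9 CPM, so that each mutant pool lay below each wildtype pool. The log2 fold change was -1.11 ± 0.295 (SE), or 0.462-fold. The two-sided exact permutation test gave p = 0.0286, the smallest that 4 pools against 4 allow. In contrast, edgeR's adjusted p over all genes was 0.0776, which is not past the threshold, and 0.0116 when adjusted over the list alone for the Cox7a family. Without mutant replicate 4, the pool with the highest cox7a1 among mutants, the log2 fold change was -1.50 with an adjusted p of 0.0144. Measured against 19 other nuclear complex IV subunits, an alternative chosen after the data were seen, cox7a1 was lower by -1.11 log2 units in mutants, with an SD of 0.286 among mutant pools in place of 0.713. The other members of the Cox7a family did not pass the test. COX7A2 (ENSDARG00000053217) had a log2 fold change of 0.28 ± 0.246 (SE), a second COX7A2 row (ENSDARG00000110700) -0.15 ± 0.21 and COX7A2L, a factor that joins complexes III and IV, -0.09 ± 0.165, with edgeR adjusted p-values of 0.603, 0.771 and 0.825.

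**Figure D1:**
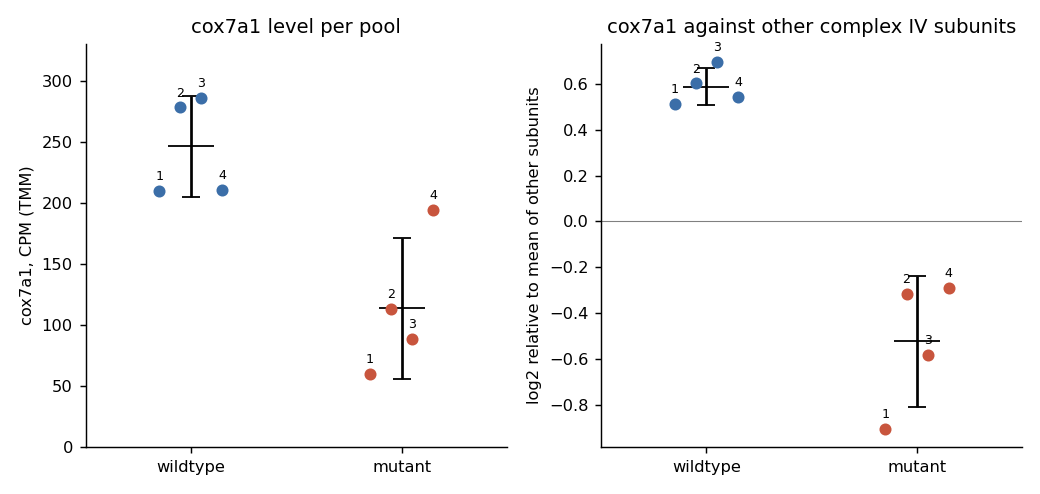
Level of cox7a1 in each pool, numbered by replicate, in CPM (left) and in log2 units relative to the mean of the other nuclear complex IV subunits (right); horizontal bars are means and whiskers SDs of 4 pools. On the left mutant replicate 4 lies at 193.9 CPM, near the wildtype pools, and on the right it lies at -0.29, with the other mutant pools between -0.90 and -0.32.

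Across the transcriptome, mutant ventricles differed from wildtype in 363 of 17949 tested genes, 205 of them higher and 158 lower. Among changed genes with an average log2 CPM of at least 1, no overlap between the genotypes and a symbol that is not a clone-style name, the highest rises were in CHD5, a chromatin remodeller (24.88 CPM in mutant against 3.003 in wildtype, 8.28-fold), SIK2, a salt-inducible kinase (11.16 against 2.444, 4.55-fold), and gstt2, a glutathione transferase (12.74 against 3.646, 3.5-fold). Both hsp70l (3.19-fold) and hspa1b (2.53-fold), which encode heat shock chaperones of the Hsp70 family, were among the 12 largest of these rises. The deepest falls under the same rule were in zbtb16b, a zinc finger transcription factor (6.571 CPM against 44.3, 0.149-fold), ITGA10, an integrin subunit (4.199 against 18.4, 0.228-fold), and igflr1 (2.872 against 12.22, 0.235-fold). Some changed genes at lower levels or with clone-style names had larger fold changes in both directions, such as btr16 (0.1483 against 1.135 CPM, 0.13-fold), chosen after its values were seen. The linker histone gene histh1l1 (19.2 CPM against 58.05) fell to 0.331-fold, and SLC25A32, a mitochondrial folate carrier, fell from 27.33 ± 1.87 to 10.36 ± 0.897 CPM (SD, n = 4).

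These genes were chosen as past the threshold, so their log2 fold changes are large against their errors by selection. Among the rises, CHD5 reached 3.05 ± 0.458 (SE; edgeR adjusted p = 0.0119), hsp70l 1.68 ± 0.182 (0.00371) and SGSM2, a regulator of Rab proteins, 1.47 ± 0.137 (0.00155). The remaining rises were nlrc8, pkn3, myo1hb, lgals3bp.2, sulf2a, which encodes an extracellular sulfatase, and the adhesion molecule chl1b, with log2 fold changes from 1.36 to 1.77. Among the falls, SLC25A32 and histh1l1 had the smallest adjusted p in the data, 0.000939 each, with log2 fold changes of -1.40 ± 0.114 and -1.60 ± 0.137. Other falls were MINDY4B, ALDH3A2, a fatty aldehyde dehydrogenase, CCSAP, the metallothionein MT1X, the urea transporter SLC14A2 and CYP26B1, which degrades retinoic acid, with log2 fold changes from -1.88 to -1.39. The groups did not overlap in 362 of the 363 changed genes, and in 11.7% of all tested genes against 2.86% by chance. Changes of at least 2-fold were found for 46 higher and 66 lower genes.

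With libraries scaled by their totals alone, 60 genes were higher and 97 lower, so the excess of higher over lower genes was not kept. The counts fell by over 1.5 times when any 1 of 6 pools was left out: 70 higher and 66 lower without wildtype replicate 1, 53 and 44 without wildtype replicate 2, 32 and 37 without wildtype replicate 3, 56 and 54 without mutant replicate 1, 100 and 71 without mutant replicate 2, and 29 and 39 without mutant replicate 3. They were 273 and 200 without wildtype replicate 4 and 231 and 149 without mutant replicate 4. Of 42 called genes taken by the naming rule or from the lists, 16 kept their call with each pool left out in turn, among them CHD5, SIK2, gstt2, hsp70l, SGSM2, SLC25A32, histh1l1, igflr1, HK2 and LMOD2, and 26 lost it in at least 1 case. The call of ITGA10 was lost in 7 of 8 cases (adjusted p up to 0.0999, without wildtype replicate 3), that of sulf2a in 7 (up to 0.105, without mutant replicate 3) and that of zbtb16b in 5 (up to 0.0946, without mutant replicate 3). MT1X, MEF2C and hif1aa also lost it in 7 cases and npas2 in 8.

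**Figure D2:**
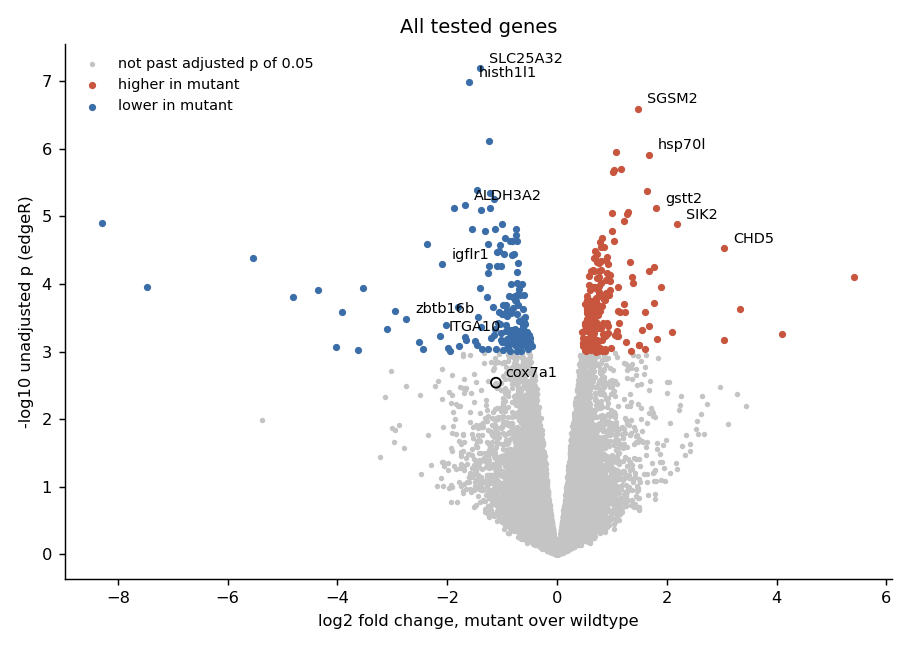
Log2 fold change (mutant over wildtype) and -log10 of the unadjusted edgeR p of each tested gene, with genes past the threshold in colour and 12 genes named. The circle marks cox7a1, at -1.11, which lies below the changed genes.

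Nuclear genes of the respiratory chain did not pass the test. None of the 22 nuclear complex IV subunits, 27 complex IV assembly factors, 37 complex I subunits, 14 complex II and III subunits or 18 ATP synthase subunits was called higher or lower by edgeR, and none when adjusted over the list alone. Among these and the 13 mitochondrially encoded subunits, 131 genes in all, 3 had an unadjusted p under 0.05 with edgeR (3235 of 17949 over all tested genes), and DESeq2 and limma-voom called 0. Their median log2 fold changes were -0.07, 0.00, -0.10, 0.01 and -0.04, and that of the 13 mitochondrially encoded subunits was -0.08. COX4I2, a complex IV subunit isoform, had -0.41 ± 0.152 (SE), cox6a1 0.41 ± 0.193, the assembly factor COX10 0.43 ± 0.143 and NDUFS8 of complex I -0.47 ± 0.251. The mean level of complex I subunits spread widely among mutant pools, at 5.58, 5.99 and 6.002 log2 CPM in replicates 1 to 3 and 6.83 in replicate 4, against 6.07 to 6.51 in wildtype. Without mutant replicate 4, camera placed the complex I list lower (median -0.45, 36 of 37 negative, adjusted p = 4.04e-11), and likewise complex IV subunits (-0.37, 3.29e-05), ATP synthase (-0.41, 3.25e-05), complexes II and III (-0.26, 0.0152), complex IV assembly factors (-0.18, 0.0488) and fatty acid oxidation (-0.22, 0.00521). Each of these 6 calls was lost with an estimated correlation (adjusted p = 0.951). Levels of long genes less those of short genes stood at 0.279, 0.018 and 0.214 log2 units in mutant replicates 1 to 3 and -0.284 in replicate 4. The genes named above (COX4I2, cox6a1, COX10 and NDUFS8) have 965, 1080, 2240 and 1575 exonic bases, against a median of 2454 in unchanged genes. Some other members of these lists are longer, such as LRPPRC (4829), NDUFA4 (3332), SDHA (2844) and ACSL1 (4809). The lengths of whole lists were not compared. No fit without replicate 4 had the length trend removed, so gene length cannot be told apart from genotype in these 6 calls. With all 8 pools and 1 surrogate variable in the fit, complex I was also lower (adjusted p = 0.00958), and this call was lost with an estimated correlation too (adjusted p = 0.975).

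In the lists of energy metabolism, single genes changed while camera called none of the lists. HK2, which phosphorylates glucose in the first step of glycolysis, rose from 7.544 to 18.32 CPM (log2 fold change 1.28 ± 0.17, SE; edgeR adjusted p = 0.00802), the 1 call among 39 glycolysis genes. Adjusted over the list alone, HK1 (0.40 ± 0.111) was also higher and PFKL (-0.71 ± 0.194) lower. Among 27 genes of the hypoxia response, pfkfb4a, a regulator of glycolytic flux, fell from 68.03 to 36.33 CPM (-0.90 ± 0.177) and hif1aa, which encodes a hypoxia-inducible factor subunit, from 53.13 to 32.25 CPM (-0.72 ± 0.16), and igfbp1b and BNIP3 were lower when adjusted over the list alone. In contrast, 16 of the 27 had positive values, with a median of 0.08. The call of pfkfb4a was lost with 5 of 8 pools left out in turn (adjusted p up to 0.0946, without mutant replicate 3) and that of hif1aa with 7 (up to 0.132, without mutant replicate 3). None of the 18 tricarboxylic acid cycle genes (median 0.02), 28 fatty acid oxidation genes (-0.11) or 16 regulators of mitochondrial biogenesis (0.04) was called, and MEF2A (0.47 ± 0.118) was higher when adjusted over the list alone. In these 3 lists 4 of 62 genes had an unadjusted p under 0.05 with edgeR (3235 of 17949 over all tested genes), and DESeq2 called 1 and limma-voom 0. Camera adjusted p-values of these 5 lists lay at 0.38 or above. Fry's test for change in either direction, which does not set a list against other genes, passed for glycolysis (adjusted p = 0.0371) and the hypoxia response (0.0223).

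In each of 2 lists of stress genes 1 gene rose, LONP1 and mthfd2. LONP1, a protease of the mitochondrial matrix, rose from 27 to 43.53 CPM (log2 fold change 0.69 ± 0.135, SE; edgeR adjusted p = 0.0285), the 1 call among 27 mitochondrial chaperone and antioxidant genes. Adjusted over the list alone, the calls were 4 higher, among them the chaperones HSPD1 (0.70 ± 0.162) and HSPA9 (0.46 ± 0.119), and 1 lower, CAT (-0.42 ± 0.131), which encodes catalase. In the list of the integrated stress response and one-carbon metabolism, mthfd2, a mitochondrial folate enzyme, rose from 44.98 to 64.26 CPM (0.52 ± 0.104, adjusted p = 0.0341), and 20 of 27 genes had positive values with a median of 0.12. SHMT1 was also higher when adjusted over the list alone. Camera gave adjusted p-values of 0.737 and 0.239 for these lists, and fry's test in either direction 0.0165 and 0.0371. With 1 pool left out the call of LONP1 was lost in 5 of 8 cases (adjusted p up to 0.099, without wildtype replicate 3) and that of mthfd2 in 6 (up to 0.108, without mutant replicate 3).

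**Figure D3:**
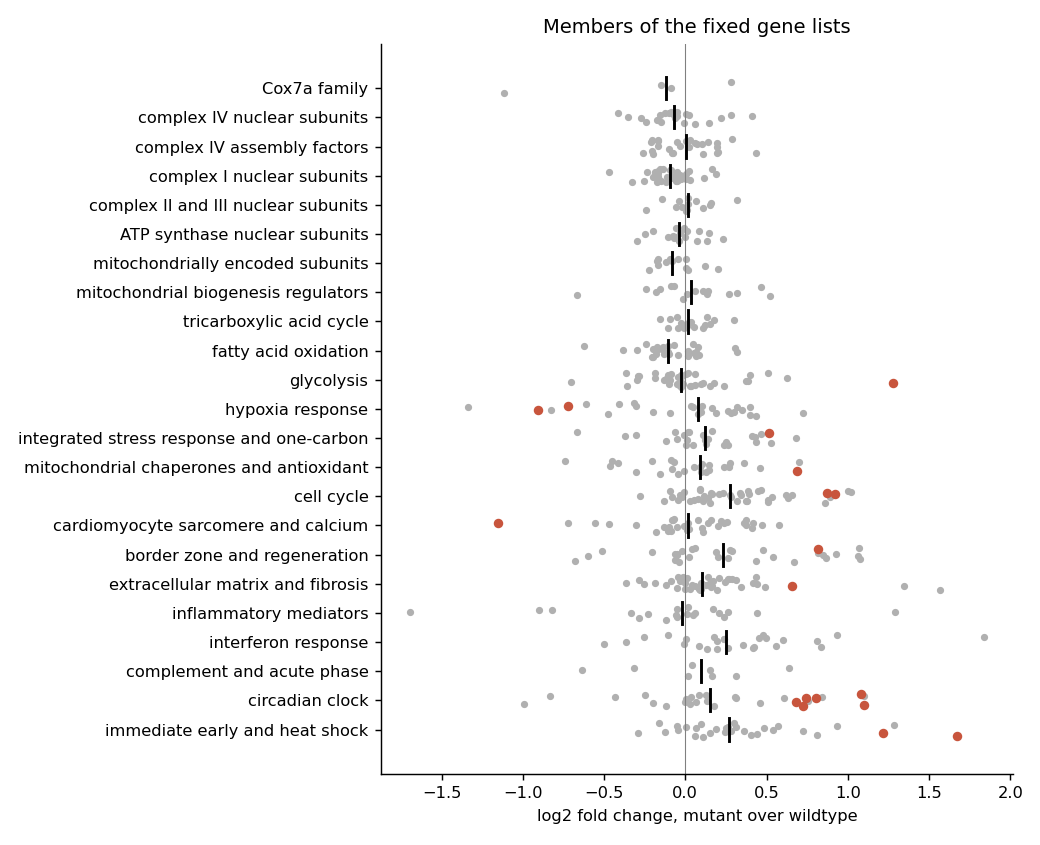
Log2 fold change (mutant over wildtype) of each tested member of the lists other than cell type lists, with members past the edgeR threshold in red and the list median as a black bar. The respiratory chain lists are centred near 0, with medians from -0.10 to 0.01 and no red point.

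At its preset correlation camera placed 3 lists higher in mutants, the cell cycle (adjusted p = 9.99e-05), the circadian clock (0.000252) and immediate early and heat shock genes (6.7e-05). With an estimated correlation none of the 3 calls held (adjusted p = 0.987, 0.661 and 0.556). In the cell cycle list, 2 of 44 genes rose, MCM5 (12.35 to 23.41 CPM; log2 fold change 0.92 ± 0.165, SE) and MCM3 (9.55 to 17.51 CPM; 0.87 ± 0.199), both parts of the helicase that opens DNA for replication, and 36 genes had positive values with a median of 0.28. Adjusted over the list alone, 5 were higher, among them MCM6 and MCM2. In the clock list, 6 of 28 genes rose: CRY2 (0.68 ± 0.104), dbpa (0.72 ± 0.115), 2 PER1 rows (0.80 ± 0.131 for ENSDARG00000012499 and 1.08 ± 0.23 for ENSDARG00000056885), NR1D1 (1.101 ± 0.234) and npas2 (0.74 ± 0.168), most of them encoding repressors of the circadian clock. Adjusted over the list alone, 9 were higher and 3 lower. None of the 6 calls held with each pool left out in turn. That of CRY2 was lost in 1 of 8 cases (adjusted p = 0.0508, without wildtype replicate 3), and that of dbpa in 2. Losses numbered 3 for PER1 (ENSDARG00000012499), 6 each for PER1 (ENSDARG00000056885) and NR1D1 and 8 for npas2 (adjusted p up to 0.129, without wildtype replicate 2). The calls of MCM5 and MCM3 were lost in 4 and 6 cases (adjusted p up to 0.0643, without mutant replicate 1, and 0.148, without wildtype replicate 3). Those of hsp70l and hsp90aa1.1 were lost in 0 cases. In the list of immediate early and heat shock genes, hsp70l and hsp90aa1.1, a cytosolic Hsp90 chaperone (367 to 854.4 CPM; 1.22 ± 0.166), rose, 25 of 30 had positive values with a median of 0.27, and 5 were higher when adjusted over the list alone.

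The mean level of the immediate early and heat shock list was higher in each mutant pool than in each wildtype pool (two-sided exact permutation p = 0.0286, adjusted p over 36 lists 0.685), and clock and cell cycle means overlapped between the genotypes (exact permutation p = 0.0571 and 0.171). Fry's adjusted p for change in either direction was 0.00219 for the clock and for immediate early and heat shock genes and 0.0666 for the cell cycle. Each of the 35 ways to split the 8 pools into 4 and 4 gave at least 3 lists past camera's threshold, so the number of lists does not set the genotypes apart.

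**Figure D4:**
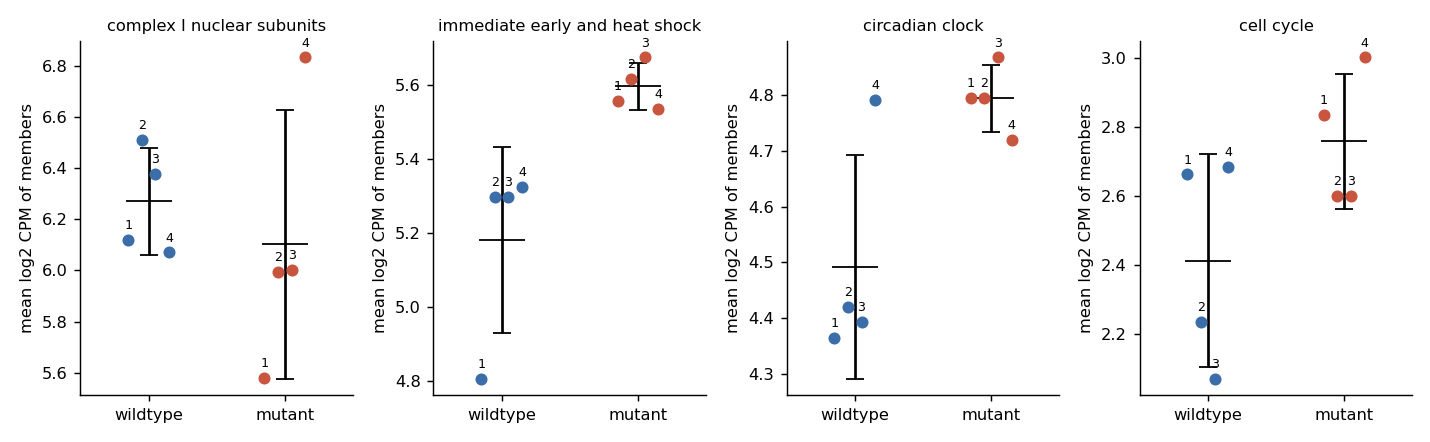
Mean log2 CPM of the tested members of 4 lists in each pool, numbered by replicate, with the mean and SD of 4 pools per genotype. Immediate early and heat shock means run from 4.81 to 5.33 in wildtype and from 5.53 to 5.67 in mutants, and mutant replicate 4 has the highest complex I mean, at 6.83.

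Among the lists of the injury response, single members changed. LMOD2, which controls the length of actin filaments in the sarcomere, fell from 81.96 to 36.81 CPM (log2 fold change -1.16 ± 0.146, SE; edgeR adjusted p = 0.0077), the 1 call among 34 sarcomere and calcium genes. Adjusted over the list alone, MYH6 (0.58 ± 0.137) was higher and myh7ba (-0.72 ± 0.184) lower, both myosin heavy chains. MEF2C, a cardiac transcription factor, rose from 106.9 to 188.4 CPM (0.82 ± 0.186, adjusted p = 0.0494) in the border zone and regeneration list, whose 30 genes had a median of 0.23. TGFB3, a growth factor of the TGF-beta family, rose from 94.71 to 149.4 CPM (0.66 ± 0.125, adjusted p = 0.0263), the 1 call among 47 extracellular matrix genes (median 0.10). With each pool left out in turn the call of LMOD2 was kept. That of MEF2C was lost in 7 of 8 cases (adjusted p up to 0.112, without mutant replicate 1) and that of TGFB3 in 5 (up to 0.0904, without wildtype replicate 2). No gene of the inflammatory mediator (20 genes, median -0.02), interferon (26, median 0.25) or complement lists (8, median 0.10) was called by edgeR. Of these 54 genes 7 had an unadjusted p under 0.05 with edgeR (3235 of 17949 over all tested genes), and DESeq2 called 4 and limma-voom 1. Adjusted over the list alone, ccl34b.1 and tnfb were lower among inflammatory mediators, mxb (1.84 ± 0.432) higher in the interferon list and cfd (-0.64 ± 0.154) lower in the complement list. Camera adjusted p-values were 0.976 for sarcomere, 0.111 for border zone, 0.123 for matrix, 0.754 for inflammatory, 0.0832 for interferon and 0.918 for complement genes, and fry's test in either direction passed for sarcomere (0.0102) and border zone genes (0.0462). Without mutant replicate 4 camera placed border zone (0.0433), matrix and interferon genes (0.00521 each) higher, and these calls were lost with an estimated correlation (adjusted p = 0.768, 0.951 and 0.951). At the preset correlation border zone genes also passed without wildtype replicate 4 (0.041) and without mutant replicate 1 (0.0181), matrix genes without wildtype replicate 4 (0.00155) and without mutant replicate 3 (0.0326), and interferon genes without wildtype replicate 1 (0.000797) and without mutant replicate 3 (3.55e-05). These calls too were lost with an estimated correlation, at adjusted p = 0.411 and 0.357 for border zone genes, 0.963 and 0.993 for matrix genes and 0.993 in both cases for interferon genes. With all 8 pools, interferon genes passed with no low-count filter (0.0228), DESeq2 (0.0241), 1 surrogate variable (0.00112) and the length trend removed (0.0473), border zone genes with the replicate block (0.0463) and matrix genes with 1 surrogate variable (0.0398). Of these, the edgeR calls were lost with an estimated correlation (adjusted p = 0.986, 0.975 and 0.995 for interferon, 0.578 for border zone and 0.975 for matrix genes). DESeq2's call was tested at the preset one only.

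Camera called no list of markers of other cell types with all 8 pools. Of 258 such markers 49 had an unadjusted p under 0.05 with edgeR (3235 of 17949 over all tested genes), and DESeq2 called 10 and limma-voom 2. By edgeR 1 of them was called, CSPG4, a proteoglycan of pericytes, which rose from 27 to 49.1 CPM (log2 fold change 0.86 ± 0.157, SE, and adjusted p = 0.0238). This call was lost with 5 of 8 pools left out in turn (adjusted p up to 0.0821, without wildtype replicate 3). CNN1, a smooth muscle protein, was also higher when adjusted over its list alone, and so was MYH6 (0.58 ± 0.137), a sarcomere gene, over the atrial cardiomyocyte list. Macrophage markers had a median of -0.22 with 25 of 35 negative (camera adjusted p = 0.123), though MPEG1, a macrophage gene, had 0.78 ± 0.218. Medians were -0.12 for neutrophil, -0.14 for lymphocyte, 0.15 for erythrocyte, -0.01 for thrombocyte, 0.00 for endothelium and endocardium, -0.04 for epicardium and fibroblast, 0.08 for smooth muscle and pericyte, -0.13 for bulbus and valve, 0.01 for atrial cardiomyocyte, -0.10 for skeletal muscle, -0.15 for Schwann cell and neuron and -0.41 for liver markers, of which 4 were tested. Without mutant replicate 1, camera placed macrophage (adjusted p = 0.0183) and skeletal muscle markers (0.00356) lower, and without mutant replicate 2 macrophage markers (0.00538) lower and erythrocyte markers (0.00538) higher; macrophage markers were also lower without wildtype replicate 2 (0.00475). These calls were lost with an estimated correlation (adjusted p = 0.98 or above). Fry's test in either direction passed for smooth muscle and pericyte (adjusted p = 0.00732), epicardium and fibroblast (0.0165), atrial cardiomyocyte (0.0186) and bulbus and valve markers (0.0424), and its test in 1 direction did not (0.986 each). Camera's direction differed in sign from the list's median for complex IV assembly, complexes II and III, glycolysis, hypoxia, sarcomere, complement, endothelium, epicardium and atrial lists, and the median differed in sign from the mean for the bulbus, glycolysis, hypoxia, endothelium, epicardium and atrial lists.

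Changed genes were more frequent on chromosome 15, which carries cox7a1, than elsewhere. On this chromosome 29 of 621 tested genes other than cox7a1 changed (4.67%, exact 95% interval 3.15 to 6.64), 8 higher and 21 lower, against 334 of 17327 genes (1.93%, 1.73 to 2.14) on all others (Fisher's exact test, two-sided p = 2.96e-05, a comparison chosen after the data were seen). They included nlrc8 and SGSM2 among the 12 named rises and zbtb16b, igflr1, MINDY4B and ALDH3A2 among the named falls. The next gene after cox7a1 is chp2 (ENSDARG00000025788, GRCz11, chromosome 15, 20406143 to 20412286, minus strand). It lies 346 bases beyond the end of cox7a1, with its own end facing it. Its level fell by 1.25 on the log2 scale (± 0.129, SE, edgeR adjusted p = 0.00351). SGSM2 starts at position 20543770 and ALDH3A2 at 20799943. Within 5 Mb of cox7a1, 9 of 160 genes changed (5.62%), and beyond it 20 of 461 (4.34%).

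**Figure D5:**
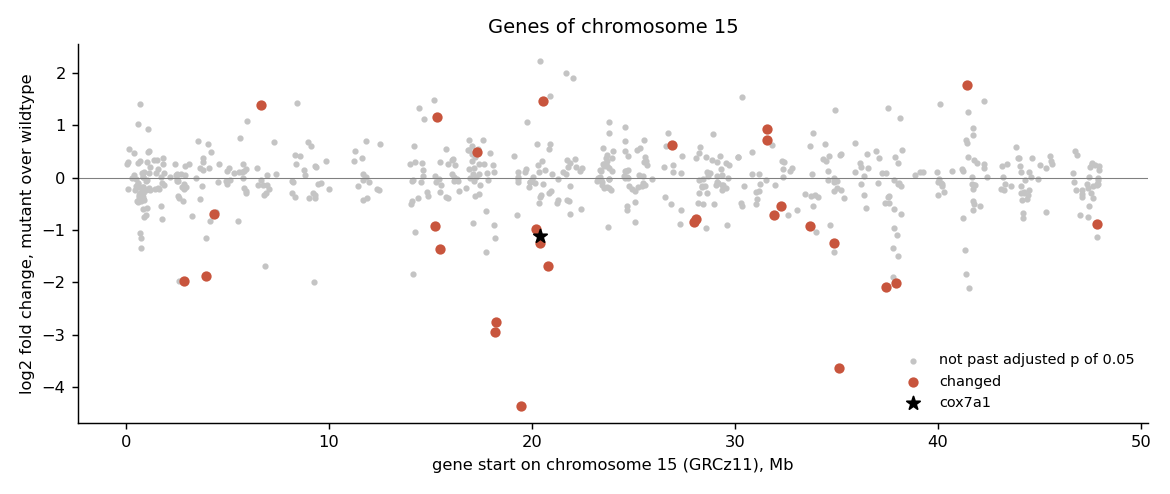
Log2 fold change (mutant over wildtype) of tested genes along chromosome 15 (GRCz11), by gene start in Mb, with changed genes in red and cox7a1 as a star. The 29 changed genes lie along the whole chromosome, and 21 of them are lower in mutants.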

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

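The tests of mixed tissue, of a rise of respiratory chain transcripts, of chromosome 15, of chp2 and of the time of day were chosen only after the results were seen. In 174 groups of 4 pools checked for a lone pool, 7 had one, and chance gives about 1 in 20. In mutant replicate 1, chl1b stood apart at 18.89 CPM from 10.52 to 11.61 in the other mutant pools. CYP26B1 stood at 87.62 CPM in wildtype replicate 2, above 44.04 to 51.44 in the other wildtype pools. NR1D1 stood at 25.85 CPM in wildtype replicate 1, below 47.34 to 49.88. The mean of the clock list was 4.79 log2 CPM in wildtype replicate 4 against 4.36 to 4.42 in the others, a level also found in mutants, and that of the immediate early and heat shock list was 4.81 in wildtype replicate 1 against 5.30 to 5.33. Neutrophil markers had a mean of 2.91 in wildtype replicate 1 against 2.09 to 2.22, and skeletal muscle markers one of 3.16 in mutant replicate 1 against 1.16 to 1.44.

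Of the 35 splits of the 8 pools, 1 gave as many changed genes as the 363 between the genotypes, which is the split by genotype itself. The highest of the others gave 27, which argues against chance for this count. It does not exclude chance, as 35 splits allow no smaller share than 1 of 35. For the 3 lists chance stays open: 35 of the 35 splits gave as many lists past camera's threshold, up to 23. The number of lists past the threshold is thus not particular to the split by genotype, and which lists passed in each split was not compared. Length profiles differed among the pools, with long minus short genes at 0.28, 0.02, 0.21 and -0.28 log2 units in mutant replicates 1 to 4 and between -0.14 and 0.01 in wildtype. With the length trend removed, 356 of the 363 changed genes were still past the threshold, which argues against a smooth trend on length as the source of most calls. The changes of called genes were large, with a median absolute log2 fold change of 0.793, so a small effect of length would hardly show in this test. Higher genes were longer, with a median of 3753 exonic bases against 2612.5 for lower and 2454 for unchanged genes, so some part of length in the rises stays open.

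The first pattern is the high cox7a1 in mutant replicate 4. If wildtype tissue mixed into this pool were its cause, other genes would lie as close to wildtype as cox7a1, which sits at 0.214 on a scale from the wildtype mean (0) to the mean of the other mutant pools (1). The 359 genes that separate the genotypes without this pool had a median position of 0.687 (bootstrap 95% interval 0.651 to 0.721), which argues against mixing as the whole cause. The bootstrap resampled genes, so its interval does not measure the spread between pools. When treated alike, the other mutant pools lay between 0.762 and 1.141. Wildtype pools, placed likewise towards their own genotype, ran from 0.579 in replicate 4 to 1.088 in replicate 3. A position of 0.687 is thus not the lowest of the 8 pools, and a smaller share of wildtype tissue stays open. The other complex IV subunits were also higher in this pool, by 0.89 of the gap of 1.204 log2 units, and the 0.31 that remained was about the SD of the other 3 mutant pools (0.294), so a shared rise of respiratory chain transcripts cannot be told apart from a rise of cox7a1 itself with so few pools. Short genes as a whole were also higher in this pool. Their median was 0.193 log2 units relative to the mean of all pools, against -0.167, -0.003 and -0.119 in mutant replicates 1 to 3. As cox7a1 has 952 exonic bases, the length profile may add to its gap, and how much was not tested. No biological explanation was tested, since the design gives none within a genotype.

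The second pattern is the concentration of changed genes on chromosome 15. A mutant chromosome copy that differs from the wildtype copy at many linked sites may account for it. The share of changed genes within 5 Mb of cox7a1 did not differ detectably from that on the rest of the chromosome (Fisher's exact p = 0.517). That window could hide a tighter cluster, and no narrower one was tested. The changed genes zgc:77784, ppp1r14ab, chp2, SGSM2 and ALDH3A2 lie between -0.95 and 0.4 Mb from cox7a1, while others lie up to 27.43 Mb away. Linkage over a whole chromosome in siblings also keeps this open. Fewer copies of the chromosome are argued against, since the median log2 fold change of its genes was -0.033 from that of all others (bootstrap 95% interval -0.066 to 0.008). For the lower chp2, transcripts of cox7a1 running on past its end are argued against. The genes lie on opposite strands, and counting used the strand. The mean log2 ratio of chp2 to cox7a1 differed by only -0.018 ± 0.39 (SE) between genotypes. However, chp2 did not follow cox7a1 within genotypes (slope of the log2 levels -0.018 ± 0.084, SE, over 8 pools). Counts of chp2 made up only of read-through would give a slope of 1, and a partial share a lower one. In mutant pools chp2 lay between 4.046 and 5.062 CPM while cox7a1 ran from 59.52 to 193.9 CPM. An effect of lost Cox7a1 on these genes stays open too, as untested.

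The third pattern is the positive median in mutants of the immediate early and heat shock list and of the clock list, whose calls did not hold with an estimated correlation. With the length trend removed, the clock list kept 79.4% of its median log2 fold change and the immediate early and heat shock list 97.4%. This argues against gene length. Hearts collected at another time of day would move the arms of the clock apart. The period, cryptochrome, nr1d and D-box arm had a median of 0.31 with 16 of 18 genes positive. The bmal, clock and npas2 arm had a median of -0.056 with 3 of 6 positive. The standard error of its mean over genes was 0.209, which does not measure the spread between pools. The 6 genes of the bmal, clock and npas2 arm go both ways, so a difference in collection time cannot be told apart from an effect of genotype. The labels used here give no time of collection. The clock arms hold no heat shock gene, so they do not bear on the immediate early and heat shock list. That list was fixed as a check of sample handling, and no test here separates handling from genotype. An effect of genotype stays open as untested.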

How the results depend on the processing

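The length trend, the chromosome 15 alternatives, the families without list members and the comparison of cox7a1 with other subunits were chosen after the data were seen. All 363 changed genes kept their direction in each alternative that tested them (346 were tested with a CPM of at least 1 in at least 4 pools). Their selection largely set this outcome, since the groups did not overlap in 362 of them. Of 42 called genes taken by the naming rule or from the lists, 14 lost their call with library totals alone, 7 with the replicate block, 6 with 1 surrogate variable, 3 with limma-voom, and from 5 to 23 with 1 pool left out. Numbers of calls moved more. Library totals alone gave 60 higher and 97 lower genes, and DESeq2 569 and 434, with all 363 changed genes among its calls. On simulated data DESeq2's calls were more often false, but those counts were drawn with edgeR's own dispersions. A threshold of 0.01 gave 14 and 16, and one of 0.1 gave 502 and 390. With 1 pool left out the number of higher genes ran from 29 to 273 and of lower genes from 37 to 200. The replicate block gave 126 higher and 84 lower genes, and 166 of its calls were among the 363. With genotype means removed, same-numbered pools correlated at 0.246, -0.071, 0.036 and -0.066, and pools did not each match their own number best. However, the surrogate variable rose with the replicate number in both genotypes, from -0.68 to 0.397 in wildtype and from -0.19 to 0.34 in mutants. An order or batch shared by number therefore stays open. The library numbers of all wildtype pools come before those of all mutant pools. An effect of that order cannot be told apart from genotype in any of these fits.

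The log2 fold change of cox7a1 passed the threshold without a low-count filter (-1.115, adjusted p = 0.0415), with DESeq2 (-1.113, 0.00266) and with the length trend removed (-1.07, 0.0451), and ran from -1.499 to -0.911 with 1 pool left out. Over the alternatives its adjusted p ran from 0.00266 to 0.22. Against other subunits it was -1.111, with the same unadjusted exact permutation p as without them (0.0286, the smallest possible), so no call was gained.

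The lists higher and lower numbered 5 and 1 (complex I, adjusted p = 0.00958) with 1 surrogate variable, and 0 were higher with an estimated correlation and with fry; with 1 pool left out they ran from 3 to 6 higher and from 0 to 6 lower. Adjusted p rose to 0.987 (cell cycle), 0.661 (clock) and 0.556 (immediate early and heat shock) with an estimated correlation, and to 0.649, 0.0787 and 0.0787 with fry. Of genes named but not past the threshold, tfa turned to -0.013 with library totals alone. With 1 pool left out these ranges crossed 0: COX7A2 (ENSDARG00000053217) from -0.068 to 0.421, COX7A2L from -0.269 to 0.001, UQCRC2 from -0.045 to 0.193, uqcrc2a from -0.044 to 0.264, tfa from -0.09 to 0.294, tnfrsf9a from -0.009 to 0.789 and vtg2 from -0.298 to 0.027. The cause was not tested. At total counts of 41556101 or more, most genes changed by 1.5-fold were not detected in simulation (10.4% recovered).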

Other observations

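Of the gene families described here, the Hsp70 and Hsp110 chaperones passed as a group both at camera's preset correlation (adjusted p = 1.92e-16) and with an estimated one (adjusted p = 0.00673). The families are from 12 collected by symbol after the values were seen, so their tests describe these pools only. This family overlaps the fixed lists, which hold 6 of its 17 tested genes, hsp70l among them. The 11 genes outside the lists were all positive, with a median log2 fold change of 0.73, and passed without the others (camera adjusted p = 7.6e-12, and adjusted p = 0.00673 with an estimated correlation). Of these 11, 5 rose: hspa1b, HSPA4 (1.00 ± 0.132, SE), HSPH1 (0.93 ± 0.191), and HSPA5 (0.83 ± 0.119) and HYOU1 (0.73 ± 0.113), which act in the endoplasmic reticulum. With each pool left out in turn the adjusted p of all 17 with an estimated correlation ran from 0.00586 to 0.0214. Their mean level was higher in each mutant pool than in each wildtype pool (two-sided exact permutation p = 0.0286, the smallest possible). For this family too, no test separates sample handling from genotype.

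Other families passed at the preset correlation and were lost with an estimated one, so only their single genes are described as changed. Of 34 aminoacyl-tRNA synthetases, which load amino acids onto tRNA, 6 rose, among them YARS1 (0.67 ± 0.109, SE), QARS1 (0.58 ± 0.106) and VARS1 (0.55 ± 0.102), and 30 had positive values with a median of 0.27 (adjusted p = 0.101 with an estimated correlation). Of 26 importins and exportins 3 rose, led by IPO13 (0.76 ± 0.127), and of 22 nucleoporins 3 rose, led by NUP210 (0.77 ± 0.138), with medians of 0.28 and 0.30 (adjusted p = 0.0855 each with an estimated correlation). Of 9 minichromosome maintenance genes, all positive with a median of 0.89, 6 are in the cell cycle list, with its 2 rises (adjusted p = 0.129 with an estimated correlation). The 3 others were also positive with a median of 0.89 and had a camera adjusted p of 0.093, with fewer members than the 5 asked of a list. Of 24 autophagy genes of the ATG and ULK families ATG2A (-0.86 ± 0.125), ULK1 (-0.67 ± 0.14) and atg9b (-0.73 ± 0.162) fell, and 21 were negative with a median of -0.32 (adjusted p = 0.054 with an estimated correlation, and 0.0391 without mutant replicate 4). The mean level of synthetases, importins, nucleoporins and nucleolar proteins was higher in each mutant pool than in each wildtype pool, and that of autophagy genes lower (two-sided exact permutation p = 0.0286 each, not adjusted over the 12 families).

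In 3 families the preset call also depended on single pools. Of 64 translation initiation factors 4 rose, among them EIF4G1 (0.71 ± 0.135, SE), with a median of 0.06 and a camera adjusted p of 0.0282 (0.519 with an estimated correlation), which was lost without wildtype replicate 1 (0.129), wildtype replicate 4 (0.0694) or mutant replicate 4 (0.298). Of 17 UTP and NOP proteins of the nucleolus UTP20 and NOP58 rose, with a median of 0.11 and an adjusted p of 0.0155 (0.22 with an estimated correlation), lost without wildtype replicate 4 (0.0998) or mutant replicate 4 (0.0725). Of 49 co-chaperones with a J domain, 2 of them in a fixed list, DNAJB4 rose (0.90 ± 0.19), with a median of 0.04 and an adjusted p of 0.0206 (0.168 with an estimated correlation), lost without wildtype replicate 1 (0.066), wildtype replicate 4 (0.0562) or mutant replicate 4 (0.0704). The 79 cytosolic ribosomal proteins (median 0.04) and 20 lysosomal ATPase subunits (-0.01) had 0 calls by edgeR, DESeq2 and limma-voom, with 0 and 2 genes at an unadjusted p under 0.05. At the preset correlation ribosomal proteins were lower without mutant replicate 4 (adjusted p = 3.14e-08) and higher without mutant replicate 1 (0.0183), and both calls were lost with an estimated correlation (adjusted p = 0.358 and 0.722).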
